A study of Drosophila mojavensis with 137 samples.

How the data were processed

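Whole adult flies of Drosophila mojavensis, a cactus-breeding fruit fly of the Sonoran Desert region, were measured on 137 one-colour NimbleGen arrays (Cy3 label, 12 arrays per slide, the 135K design). The values used here are the log2 expression values the authors deposited, 1 value for each of 14528 transcripts on each array. Per the submitters' processing notes, these log2 values were made with RMA, a procedure that corrects background, equalises the distributions of the arrays and summarises the probes of a transcript. Its software version, its settings and the annotation release behind the transcript IDs are not given in the sources used here. The values lay between 5.829 and 15.89, with 0 missing. Because RMA sets the arrays to a near-common distribution, a change of total RNA per fly cannot be seen in them, and fold changes of dim transcripts are compressed by the background. Scanner signals, slide positions and scan dates were not analysed here, so slide effects could not be tested.

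Groups were taken from the sample titles and characteristics. They give the population (Las Bocas in Sonora or Punta Prieta in Baja California), the rearing cactus (agria or organ pipe), the sex, the mating state and the egg-to-adult development time in days. There were 52 groups of 1 to 5 arrays, and 10 of them held 1 array. The descriptions of 3 arrays contradicted their titles and characteristics. These were the Las Bocas agria virgin female array of 16 days, replicate 3, and the Las Bocas organ pipe mated female arrays of 16 days, replicates 1 and 2, and all were kept as titled. No array was identical to another (0 identical columns), and the highest Pearson r within a group was 0.995. The labels do not say whether replicates came from separate cultures or pools of flies, so p-values measure only the spread between these arrays and nothing beyond them. The number of arrays limits the precision.

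The test was limma (version 3.58.1, in R 4.3.3), lmFit followed by eBayes, with Benjamini-Hochberg adjustment over the 14528 transcripts and a threshold of 0.05 on the adjusted p. Within each sex the model held population, diet and mating state as 2-level terms and development time as a linear term in days, and all arrays shared 1 estimate of the spread. The sexes were compared at 16 days, at equal weight of populations, diets and mating states. The difference of each effect between the sexes was tested as a contrast. A second model added the products of diet and development time, population and development time, and population and diet, common to both sexes. Effects are log2 differences with standard errors from the fit, given as female minus male, mated minus virgin, organ pipe minus agria, Punta Prieta minus Las Bocas, and per day longer. The design, the alternatives and the rule for the transcripts named were fixed before the data were examined.

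The files do not pair the transcript IDs with gene names, and 0 of the 14528 IDs matched the 15130 genes of the reference table used here. The 27 gene lists fixed beforehand (0 with a measured member), their camera tests and both alternatives of those tests were therefore not run. Transcripts are given by ID, at most 2 that were higher and 2 that were lower for each effect, those with the largest effects past the threshold. For the differences between the sexes the rule took the 3 with the smallest adjusted p, reduced to 2 where all 3 had 1 direction. In place of gene lists, transcripts were put into classes by their sex contrast, a choice made after seeing the data. The classes were female-biased or male-biased by over 4-fold, biased by less than that, and little sex bias (a log2 difference within 0.5 or not past the threshold), and each was tested with camera at a preset and at an estimated correlation.

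Array-level scores were computed from the deposited values of transcripts chosen by the fits. The sex score is the mean of 302 strongly female-biased transcripts minus that of 1417 strongly male-biased ones. The population score is the mean deviation, in the direction of Punta Prieta, of 54 transcripts that differed between the populations by over 0.7 in the same direction in both sexes (adjusted p below 0.01) and between the sexes by less than 1. The mating score does the same with 95 transcripts in females and 85 in males that differed by over 0.5, and all these sets were taken from the 135 arrays described next. On the first principal component 2 arrays lay on the side of the sex opposite to their labels. They stay in every count given as the main value, and counts without them (135 arrays) were added after seeing the data.

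Alternatives fixed beforehand were other scalings, a filter on dim transcripts, another variance model, array weights, subsets of days, labels and mating states, matched cells, development time as categories, the replicate number as a block, and each replicate number left out in turn. Leaving out the 4 female arrays with a sex score below 2.5 (133 arrays, or 131 without the 2 arrays as well), array spread (the SD of an array's log2 values) as a covariate, fits without the 2 arrays, an F test over days within population, diet and mating state, and a comparison of 18 with 16 day males were added after seeing the data. The fits were tested on simulated data made from the shuffled residuals of the real arrays, with 200 of 14528 transcripts changed by a known amount. With 137 arrays, a slope of 0.2 per day was recovered for 78% of changed transcripts in females and 84% in males, with 2 and 1 other calls. At 0.1 per day 14.5% and 31% were recovered. A mating effect of 0.4 was recovered for 82% in females and 82.5% in males, and a diet effect of 0.4 for 73.5% in females and 80.5% in males. At 0.2 a mating effect was recovered for 19.5% in females and 20% in males, and a diet effect for 9% and 18.5%. Other transcripts called with 137 arrays numbered at most 13 per simulation, apart from 123 beside 126 true ones for population by development time at 0.2. For each count, 100 splits of the arrays, the real one included, were also fitted.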

Results

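The study asked how the adult transcriptome of Drosophila mojavensis depends on how long a fly took to develop, on its population of origin, on the cactus it was reared on, on its sex and on whether it had mated. The arrays comprised 62 of females (20 mated, 42 virgin) and 75 of males (22 mated, 53 virgin). Las Bocas supplied 59 arrays and Punta Prieta 78, and 68 were of flies reared on agria and 69 on organ pipe. Development time was 14 days on 22 arrays, 15 days on 48, 16 days on 43, 17 days on 18 and 18 days on 6. The 18 days stand in the titles, characteristics and descriptions of those arrays, but the series' design text lists 14 to 17 days only. The factors were not fully crossed. All 18 day flies were virgins reared on organ pipe, and all 17 day females were reared on organ pipe. Las Bocas flies reared on organ pipe had no 14 day array, and their mated arrays were all of 16 days. In the fit as designed, diet, mating and development time are thus separated only by assuming additive effects where such groups are missing. Array medians lay between 11.24 and 11.5 on the log2 scale.

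Sex separated the arrays along the first principal component, which held 82.55% of the variance, but 2 arrays lay with the opposite sex. The array labelled Las Bocas organ pipe mated female, 16 days, replicate 1, had a sex score of -2.66, within the male range of -3.354 to -2.533. The array labelled Punta Prieta organ pipe mated male, 16 days, replicate 2, had a sex score of 3.32, within the female range of 2.073 to 3.805. Their population scores, 0.27 and -0.628, also lay inside the range of the population that their label does not name, 0.1635 to 0.7802 for Punta Prieta and -0.8105 to -0.2771 for Las Bocas. The number of transcripts past the threshold for each effect is therefore given with all 137 arrays and with the other 135, and values with no number of arrays beside them are from 137. A further 4 female arrays had the lowest sex scores of their sex, 2.07 to 2.34 against a female mean of 3.19, and the lowest SDs of log2 values, 1.597 to 1.647. They are labelled Las Bocas agria mated female, 14 days, replicate 1, and 15 days, replicates 1 and 2, and Punta Prieta agria virgin female, 14 days, replicate 1, and counts without them were added after seeing the data. Male arrays also stood apart: Punta Prieta organ pipe virgin male, 16 days, replicate 3, and 17 days, replicate 1. Their sex scores were -2.533 and -2.587 against a male mean of -3.137, and their SDs 1.67 and 1.682. No fit left out these male arrays alone, so how far the counts in males rest on them is unknown.

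**Figure D1:**
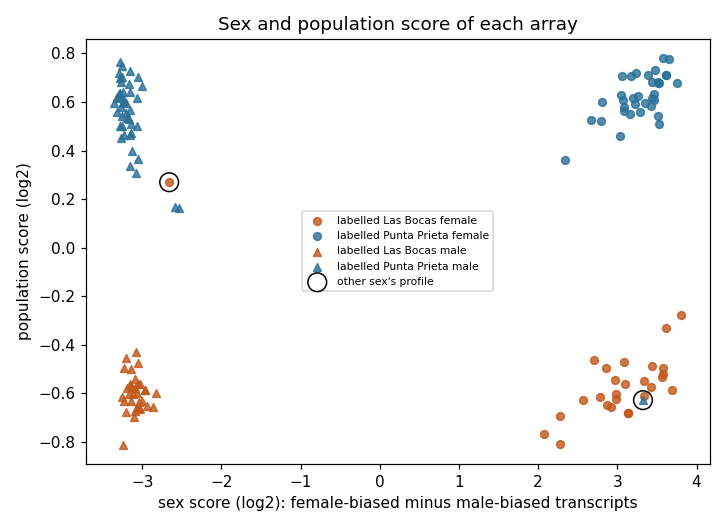
Sex score (log2, x axis) against population score (log2, y axis) for each of the 137 arrays, with shape for labelled sex and colour for labelled population. The circled arrays, at sex scores of -2.66 and 3.32, lie with the sex and the population that their labels do not name.

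Most transcripts differed between the sexes. Of 14528 transcripts, 8539 were higher in females and 4305 higher in males at 16 days (8589 and 4306 with 135 arrays). The strongest differences were mostly on the male side, with 1364 transcripts over 4-fold higher in males against 271 in females, and 258 against 39 over 16-fold (1417 against 302, and 349 against 47, with 135 arrays). Among female-biased transcripts, FBtr0161796 had a mean of 15.15 ± 0.765 (SD, n = 62) in females and 8.883 ± 0.8 (SD, n = 75) in males, a log2 difference of 6.18 (SE 0.161, adjusted p = 1.59e-69). FBtr0174527 was higher in females by 6.12 (SE 0.199, adjusted p = 1.41e-60). Among male-biased transcripts, FBtr0169045 was at 14.79 ± 0.685 (SD, n = 75) in males and 7.712 ± 1.4 (SD, n = 62) in females, a difference of -7.04 (SE 0.223, adjusted p = 8.1e-62), and FBtr0172595 differed by -6.91 (SE 0.225, adjusted p = 1.76e-60). Without the 2 arrays these differences were larger, 6.49 for FBtr0161796 and -7.38 for FBtr0169045. Sex accounted for 82.1% of the variance over all transcripts in the 135 arrays, against 1.32% for population, 0.709% for mating, 0.449% for diet and 0.428% for development time.

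Mated females differed from virgin females in 1997 transcripts, 569 of them higher and 1428 lower after mating, but the number and the balance of directions rested on a few arrays. Without the 4 female arrays of low sex score, 3 of them mated, 797 passed (395 higher, 402 lower), and without these and the 2 arrays 637 (447 higher, 190 lower). With array weights 1335 passed (715 higher, 620 lower). FBtr0168945, itself female-biased, rose from 11.06 ± 1.06 (SD, n = 42) in virgin to 12.96 ± 1.19 (SD, n = 20) in mated females, by 1.87 (SE 0.233, adjusted p = 4.02e-10), with 19 of 20 mated female arrays above the virgin mean. FBtr0167058 rose by 1.63 (SE 0.212, adjusted p = 1.76e-09). FBtr0163649 fell by 1.72 (SE 0.219, adjusted p = 7.47e-10) and FBtr0163647 fell by 1.35 (SE 0.241, adjusted p = 1.68e-05). The second of these did not pass without the arrays of replicate number 1 (adjusted p = 0.0529). All the transcripts named here are female-biased, and the mated female arrays include the first of the 2 arrays, which has a male profile. Without the 2 arrays the rises were larger, 2.10 for FBtr0168945 and 1.895 for FBtr0167058. The falls were then smaller, at -1.49 for FBtr0163649 and -1.24 for FBtr0163647. Of 4793 transcripts female-biased up to 4-fold, 1006 passed as lower and 62 as higher, and of the 271 over 4-fold 122 fell and 34 rose. Male-biased transcripts over 4-fold were on the other side, 72 higher and 0 lower of 1364. With camera at the preset correlation the shifts of the moderately female-biased and the strongly male-biased class had adjusted p of 4.99e-15 and 5.5e-28, and with an estimated correlation the adjusted p were 0.606 and 0.868. Leaving out the 2 arrays reduced the count to 1225, of which 489 were higher and 736 lower, and the male-biased transcripts over 4-fold that rose to 31 of 1417. The female-biased class up to 4-fold then had 449 lower and 90 higher of 4926, and that over 4-fold 102 lower and 50 higher of 302. Without the 4 arrays of low sex score as well, the class up to 4-fold had 104 lower and 97 higher of 4831, and the male-biased transcripts over 4-fold 5 higher and 1 lower of 1438. Leaving out every array with replicate number 1, the 51 that include the first of the 2 arrays, gave 193 transcripts (154 higher, 39 lower).

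Mated males differed from virgin males in 1270 transcripts, 995 higher and 275 lower. FBtr0174264 rose by 1.33 (SE 0.162, adjusted p = 3.14e-10), from 9.394 ± 0.617 (SD, n = 53) to 10.66 ± 0.983 (SD, n = 22), and FBtr0173947 rose by 1.14 (SE 0.184, adjusted p = 1.34e-06). FBtr0174510 fell by 1.70 (SE 0.141, adjusted p = 8.43e-19), with means of 12.3 ± 0.711 (SD, n = 53) in virgin and 10.45 ± 0.703 (SD, n = 22) in mated males, and 22 of 22 mated arrays lay below the virgin mean. FBtr0173441 fell by 1.17 (SE 0.148, adjusted p = 1.2e-09). Of 6773 transcripts with little sex bias 563 were higher and 183 lower, and of 4793 moderately female-biased ones 380 were higher and 21 lower, where 8.74% of all transcripts passed. With camera the shifts of these classes had adjusted p of 0.409 and 0.000412 at the preset correlation, and adjusted p of 0.923 and 0.868 with an estimated correlation. With 135 arrays the moderately female-biased class had 315 higher and 77 lower of 4926, and its shift did not pass at the preset correlation either (adjusted p = 0.953). The count was 1353 without the 2 arrays (982 higher, 371 lower), 2884 with array weights and 494 without the arrays of replicate number 1.

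The effect of mating differed between females and males for 3364 transcripts, 985 with a more positive effect in females and 2379 with a more negative one. FBtr0168717 rose by 0.42 in mated females (SE 0.0507) and fell by 0.17 in mated males (SE 0.0484), and the difference of 0.59 (SE 0.0701) had an adjusted p of 8.35e-10. FBtr0169070 rose by 0.85 in females (SE 0.097), with a value of -0.15 (SE 0.0926) in males that did not pass with 137 arrays (adjusted p = 0.321) and did with 135 (adjusted p = 0.0167), and the difference was 1 (SE 0.134, adjusted p = 7.52e-08). With 135 arrays the count was 1542 (452 and 1090), and without the arrays of replicate number 1 it was 77. Without the 4 female arrays of low sex score it was 1430, and without these and the 2 arrays 553 (261 and 292). Across transcripts, which are not independent replicates, the mating effects of the sexes correlated at r = -0.097 with 135 arrays and -0.344 with 137. Of the 179 transcripts past the threshold in both sexes with 135 arrays, 121 were higher in both (33.1 expected of independent lists), 20 lower in both (18.8 expected) and 38 opposite (62.2 expected). The lists are not independent, since both sexes share 1 estimate of the spread per transcript. Overlap above these expected counts can therefore arise without shared effects.

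**Figure D2:**
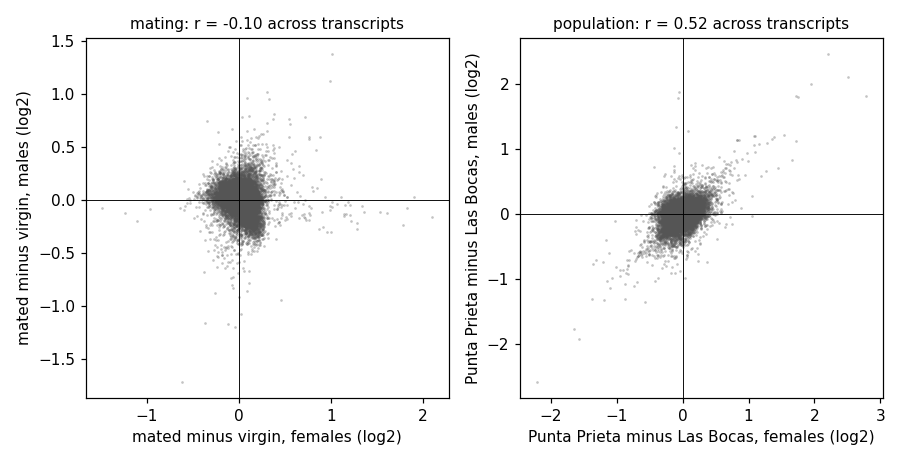
Effects in females (x axis, log2) against effects in males (y axis, log2) for each of 14528 transcripts, fitted on 135 arrays, for mating and for population. Across transcripts r is -0.097 for mating and 0.517 for population.

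The populations differed in 3319 transcripts in females, 1750 higher and 1569 lower in Punta Prieta, and in 2480 in males, 1004 higher and 1476 lower. In females FBtr0164933 was at 9.229 ± 0.269 (SD, n = 35) in Punta Prieta and 6.507 ± 0.379 (SD, n = 27) in Las Bocas, a difference of 2.71 (SE 0.0847, adjusted p = 1.11e-59), with 35 of 35 Punta Prieta arrays above the Las Bocas mean. FBtr0167831 was higher in Punta Prieta by 2.34 (SE 0.153) in females and 2.06 (SE 0.143) in males. FBtr0167365 was lower there by the largest amount in either sex, at -2.12 (SE 0.124, adjusted p = 1.12e-31) in females and -2.54 (SE 0.115, adjusted p = 4.31e-42) in males. FBtr0175016 differed by -1.55 (SE 0.118) in females. In males FBtr0175546 was higher by 2.42 (SE 0.101, adjusted p = 2.49e-45) and FBtr0172679 differed by -1.90 (SE 0.0975, adjusted p = 5.08e-37). Without the 2 arrays the counts were 3227 in females (1542 higher, 1685 lower) and 3231 in males (1346 higher, 1885 lower). Without the arrays of replicate number 1 they were 541 and 1596, and with array weights the count in males was 6086.

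Of the transcripts past the threshold for population in both sexes, most had 1 direction. With 135 arrays 1082 were called in both, 488 higher in both (143 expected of independent lists), 506 lower in both (219 expected) and 88 opposite (356 expected), and r across transcripts was 0.517. Here too the shared estimate of the spread can raise the overlap, in the same or in opposite directions. All 22 transcripts with an effect over 1 log2 in both sexes had the same direction in both. The population effect nevertheless differed between the sexes for 1239 transcripts (819 more positive and 420 more negative in females), and for 1796 with 135 arrays (930 and 866). With array weights it was 4070, most of them more negative in females (1691 and 2379), with 15 and 16 day arrays only 182, and without the arrays of replicate number 1 it was 128. FBtr0173961 was higher in Punta Prieta males by 0.93 (SE 0.0527, adjusted p = 6.56e-33) and differed by -0.04 (SE 0.0565) in females, and the difference of -0.97 (SE 0.0773) had an adjusted p of 4.43e-20. FBtr0167236 was higher in Punta Prieta males by 1.31 (SE 0.0957) and differed by -0.18 (SE 0.103) in females, a difference of -1.49 (SE 0.14, adjusted p = 1.55e-15). In females the transcripts over 4-fold male-biased were lower in Punta Prieta, 588 of 1364 against 2 higher (568 of 1417 against 22 with 135 arrays, and 287 of 1438 against 26 without the 4 arrays of low sex score as well). That shift had an adjusted p of 1.88e-35 with camera at the preset correlation, and an adjusted p of 0.868 with an estimated correlation.

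**Figure D3:**
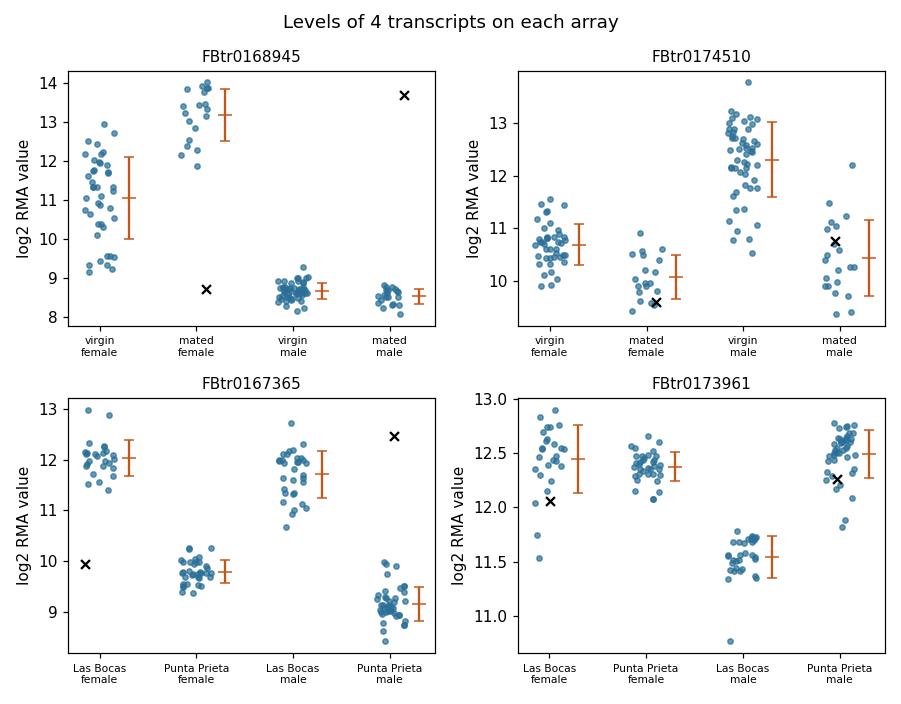
Log2 RMA values (y axis) of 4 transcripts on each array, by sex and by mating state (FBtr0168945, FBtr0174510) or population (FBtr0167365, FBtr0173961). Points are arrays, bars are mean ± SD over 135 arrays, crosses are the 2 arrays with the profile of the opposite sex, and in males FBtr0174510 was lower after mating and FBtr0173961 higher in Punta Prieta.

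The number of transcripts past the threshold for the rearing cactus was small in the fit as designed and differed widely between alternatives. In females 1 transcript passed, FBtr0164347, higher on organ pipe by 0.25 (SE 0.0497, adjusted p = 0.0168), at 11.96 ± 0.183 (SD, n = 29) against 11.72 ± 0.237 (SD, n = 33) on agria, with 25 of 29 organ pipe arrays above the agria mean. It lost the threshold in 7 of 23 alternatives, with a limma adjusted p of up to 0.547. In males 36 passed, 35 higher and 1 lower on organ pipe. FBtr0166287 was higher by 0.69 (SE 0.14, adjusted p = 0.00389), with 28 of 40 organ pipe arrays above the agria mean, FBtr0166224 by 0.66 (SE 0.148, adjusted p = 0.0124), and FBtr0175494 differed by -0.22 (SE 0.0533, adjusted p = 0.0413). At an unadjusted p below 0.05 there were 2981 transcripts in females and 832 in males, where 726 are expected with no effect. With 135 arrays the counts were 50 in females (20 higher, 30 lower) and 46 in males, and with each array centred on its median 11 in females (8 higher, 3 lower). With array weights they were 5761 in females (2501 higher, 3260 lower) and 2819 in males (1229 higher, 1590 lower). Most of those in males were thus further transcripts, and the named ones in males kept their direction under every alternative. In males they were 270 with virgin arrays only, 7 with 15 and 16 day arrays only and 1 without the arrays of replicate number 3, and in females they were 625 with array spread as a covariate, chosen after seeing the data, and 383 without the arrays of replicate number 4. By limma 0 passed in females with 15 and 16 day arrays only, with each sex fitted on its own and in matched cells. The same held without the 4 female arrays of low sex score. As a class, transcripts with little sex bias lay higher on organ pipe in females, by a median of 0.03, with 1 of 6773 members past the threshold, and moderately female-biased ones had a median of -0.09 (adjusted p = 0.465 with an estimated correlation). The first shift had an adjusted p of 8.01e-10 at the preset and an adjusted p of 0.0366 at an estimated correlation. With 137 arrays this was the only class call of any effect to hold with an estimated correlation. The diet effect differed between the sexes for 0 transcripts in limma (1968 at an unadjusted p below 0.05) and 0 with 135 arrays (1552), and for 1950 with array weights.

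Development time was associated with 0 transcripts in females and 0 in males by limma at an adjusted p below 0.05, with smallest adjusted p of 0.252 and 0.219, and with 135 arrays 0 and 0 as well (3409 and 1275 at an unadjusted p below 0.05). With 137 arrays, at an unadjusted p below 0.05 there were 2538 transcripts in females and 981 in males. The 95% interval of the slope lay within 0.2 log2 per day, a fold of 1.15, for 11746 of 14528 transcripts in females and 14171 in males. In simulated data a slope of 0.1 per day was recovered for only 14.5% of changed transcripts in females and 31% in males. Slopes of that size could therefore be missed. With array weights, 2977 transcripts passed in females (1865 higher and 1112 lower with longer development), and the highest count among other splits of the arrays so weighted was 2599. An F test over days as categories in limma gave 0 transcripts in females (1124 at an unadjusted p below 0.05) and 2 in males. Leaving out each replicate number in turn gave 0 to 46 in males. An F test over all differences between days within each population, diet and mating state, chosen after seeing the data, gave 30 transcripts in females and 0 in males (674 at an unadjusted p below 0.05), and 1050 and 2 with 135 arrays. It was not run without the 4 female arrays of low sex score, all of 14 or 15 days, nor with array spread as a covariate. Over the 135 arrays, spread in females averaged 1.743 at 14 days, 1.767 at 15, 1.792 at 16, 1.788 at 17 and 1.837 at 18. Day and array spread were thus not separated in that F test. In 18 day males, on 4 arrays, 110 transcripts differed from 16 day males (7 higher, 103 lower), but 0 did without the array labelled Las Bocas organ pipe virgin male, 18 days, replicate 2, and 0 without that of Punta Prieta, replicate 2. Without replicate 1 of Las Bocas 758 did, and without replicate 1 of Punta Prieta 574. The slope differed between the sexes for 0 transcripts in limma (2096 at an unadjusted p below 0.05) and 0 with 135 arrays (2771), and for 304 with array weights.

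The products of diet with development time, population with development time and population with diet each gave 0 transcripts in limma. At an unadjusted p below 0.05 there were 735, 246 and 372, and the 135 arrays also gave 0 for each (1351, 372 and 701 unadjusted). In simulated data with 137 arrays, a difference of 0.4 per day was recovered for 93.5% of changed transcripts for diet by development time, and a population by diet difference of 0.4 for 42.5%. At 0.2 these shares were 50% and 2.5%, and at 0.1 per day diet by development time had 1%. Population by development time had 63% at 0.2 and 5% at 0.1 per day. Smaller differences could therefore be missed.

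**Figure D4:**
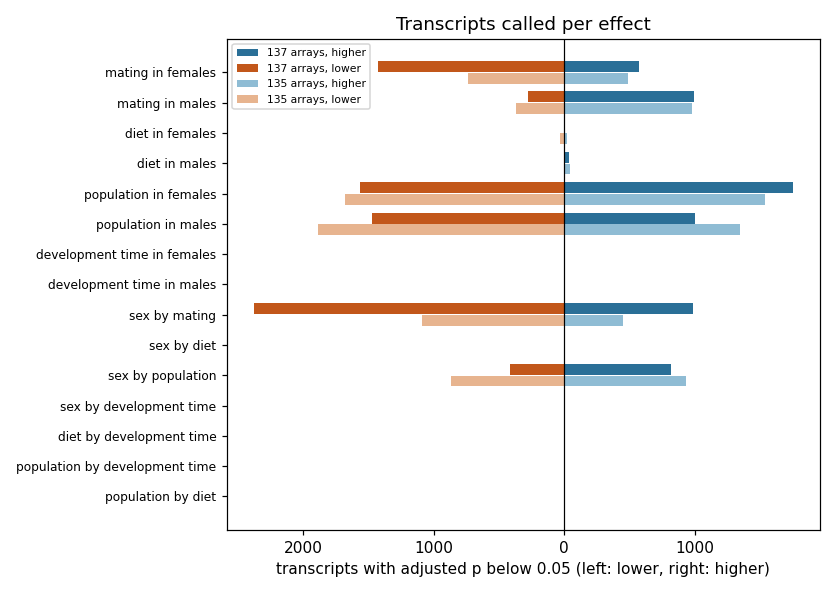
Number of transcripts with an adjusted p below 0.05 (x axis, lower to the left of 0 and higher to the right) for each effect other than sex itself, with 137 and with 135 arrays. Mating in females falls from 1997 to 1225 and sex by mating from 3364 to 1542, while development time and the 3 products stay at 0.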

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

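The tests of the 2 arrays with the profile of the opposite sex, and of array spread behind the population counts, were chosen after the result was seen, as were the counts with 135 arrays and those without the 4 female arrays of low sex score. The other tests here were written down before their results were seen, but the requirement that a median pass its bound by more than its bootstrap error was set after the medians of the male-biased transcripts were seen, and it left male RNA in mated females open where the bound alone would have argued against it.

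The effect of mating differed between the sexes for 3364 transcripts and that of population for 1239. Among named transcripts, the mating effect was more positive in females than in males by 1.81 for FBtr0168945, 1.40 for FBtr0167058, 1.06 for FBtr0174510, 0.973 for FBtr0173441, 0.59 for FBtr0168717 and 1 for FBtr0169070. It was more negative in females, by a difference of -1.90 for FBtr0163649 and -1.42 for FBtr0163647. Without the 2 arrays with the profile of the opposite sex, the difference was 2.26 for FBtr0168945 and 1.87 for FBtr0167058. It was then -1.41 for FBtr0163649 and -1.11 for FBtr0163647. The population effect differed by 0.927 for FBtr0164933, which was higher in Punta Prieta in both sexes, by -0.971 for FBtr0173961 and by -1.49 for FBtr0167236.

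Within groups of 4 or 5 arrays, 3 arrays stood far from the others of their group in 60 combinations of group and measure, and chance picks out about 1 in 20, or 3. The Las Bocas agria virgin female array of 16 days, replicate 1, had an SD of 1.771 against 1.797 to 1.8. The Punta Prieta organ pipe virgin female array of 15 days, replicate 4, had an SD of 1.699 against 1.789 to 1.808. The Punta Prieta agria virgin male array of 16 days, replicate 1, had a sex score of -3.075 against -3.278 to -3.254.

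The first pattern is the pair of arrays with the profile of the opposite sex. An even mixture of RNA of both sexes is argued against, since the array nearer to its label lay 92.5% of the way from its labelled sex to the other, and its partner 102%. A small admixture in the first of these stays open. Its sex score of -2.66 lay inside the male range only through male arrays at -2.533 and -2.587, against a male mean of -3.137. The contradicting description of the array labelled Las Bocas organ pipe mated female, replicate 1, names a virgin Punta Prieta male, but its mating score of 0.557 lay above every virgin male (highest 0.117). An exchange of the labels of these 2 arrays may account for the pattern: 2 of 2 population scores lay in the range of the other label's population, and both arrays share diet, mating state and day. It remains a hypothesis, and the arrays were not relabelled.

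The second pattern is a shift of strongly male-biased transcripts in Punta Prieta females, a class call that is lost with an estimated correlation (adjusted p = 0.604 with 135 arrays). With 135 arrays 568 of these 1417 transcripts passed as lower and 22 as higher, and their median effect was -0.169 (bootstrap SE 0.0693), or -0.114 (SE 0.0651) without the 4 female arrays of low sex score, 3 of them mated Las Bocas females. Low signal in females is argued against, since transcripts with a sex contrast within 0.25, matched on level (808 different ones), had a median of 0.047 (SE 0.0244). Array spread and male RNA in mated females stay open: the median was -0.0615 (SE 0.0279) with array spread as a covariate and -0.0926 (SE 0.0723) in the 42 virgin females, neither past its bound by more than its error. A difference between the populations themselves also stays open, untested.

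The third pattern is the difference between the populations itself. Array spread is argued against as the whole cause, since with it as a covariate the count with 137 arrays was 60% of its size in females and 138% in males. Sequence variants under the probes were assumed to act alike in both sexes, which was not tested. They were examined in 950 bright transcripts with a sex contrast within 0.25, chosen by a population call in either sex with 135 arrays. Of these, 32.4% differed between the sexes (exact 95% interval 29.5 to 35.5, for counting error only). Without the 4 arrays of low sex score 28% of 843 did. These shares cannot decide the question, since choosing by a call in either sex favours effects estimated as large in that sex only. Another split of the 135 arrays also gave 2508 sex by population transcripts, above the 1796 of the real labels. Sequence variants thus stay open for the transcripts whose effect differs between the sexes. For the 994 transcripts called in both sexes with the same direction with 135 arrays, such variants and expression cannot be told apart, because the probe sequences were not analysed here. A genetic difference in expression may account for part of them and stays untested.

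Splits of the arrays gave the following. In 100 splits of the 137 arrays, the real one included, 1 gave as many transcripts as the real labels for sex (12844, highest other 7781), mating in females (1997, 953), mating in males (1270, 87), diet in males (36, 1), population in females (3319, 1747), population in males (2480, 1), sex by mating (3364, 1) and sex by population (1239, 348). No other split thus reached these counts. However, 100 splits resolve no share finer than 1 in 100, and with 135 arrays, given below, some other splits did. For diet in females 8 of 100 gave at least the real count of 1, with up to 3625, so chance cannot be excluded. For the 7 results with 0 transcripts any split gives at least as many, so the share of splits says nothing about them. Other splits gave up to 976 for development time in females, 3 for development time in males, 2187 for sex by diet and 1693 for sex by development time. For diet by development time they gave up to 471, for population by development time 38 and for population by diet 882. Splits that called many times the real count may reflect a structure of the arrays other than the labelled factors, which was not tested. With 135 arrays, 4 of 100 splits reached the count for mating in females (1225, highest other 2683), 3 for diet in males (46, 1923), 6 for diet in females (50, 2576), 2 for population in females (3227, 3553) and 2 for sex by population (1796, 2508). Some other splits thus gave more transcripts than the real labels for each of these, and that the share of splits is under 0.05, except for diet in females, rests on 100 splits of arrays that may have such a structure.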

How the results depend on the processing

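The fits without the 2 arrays with the profile of the opposite sex, without the 4 female arrays of low sex score, with array spread as a covariate, the F tests within population, diet and mating state, and the comparison of 18 with 16 day males were chosen after seeing the data. The 28 named effects gave 618 values under the alternatives, of which 595 kept direction and side of the threshold, 23 lost the threshold and 0 reversed. Except FBtr0163647 for mating in females, those that lost it were of diet. The count for sex stayed within 1.5 times under all 22 alternatives (9674 to 13150), and the 3 products of diet, population and development time stayed at 0. Where a count moved, the cause was not tested. Where fewer arrays or transcripts entered, the smaller number was not separated from the loss of those particular arrays or transcripts.

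Array weights gave 2884 transcripts for mating in males, 5761 for diet in females, 2819 for diet in males, 6086 for population in males, 2977 for development time in females, 1950 for sex by diet, 4070 for sex by population and 304 for sex by development time. The lowest weights, 0.0272 and 0.0275, fell on the 2 arrays with the profile of the opposite sex. In 20 splits so weighted, the highest other counts were 818 for diet in females, 11 for diet in males, 2599 for development time in females and 2488 for development time in males, where the real labels gave 0 in limma (381 at an unadjusted p below 0.05).

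Without the 3 arrays with contradicting labels, 1207 transcripts passed for mating in females, 77 for diet in females and 2122 for sex by mating. With 15 and 16 day arrays only, 273 passed for mating in males, 0 for diet in females in limma (2955 at an unadjusted p below 0.05), 7 for diet in males, 1052 for population in females and 182 for sex by population. With virgin arrays only, 4 passed for diet in females, 270 for diet in males, 1081 for population in females, 1 for development time in males, 14 for sex by diet and 421 for sex by population. With each sex fitted on its own, 1196 passed for mating in females, 0 for diet in females in limma (2494 unadjusted) and 18 for diet in males. Matched cells gave 0 for diet in females in limma (3107 unadjusted), and centring each array on its median gave 11. The F test over days as categories gave 2 for development time in males.

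With the replicate block, 94 transcripts passed for diet in females, and the other counts stayed within 1.5 times, among them 2126 for mating in females and 3435 for population in females. On average the replicate numbers showed no pairing of arrays of different groups. Deviations from the group means correlated at a mean r of -0.00475 with the same number and 0.00204 with different numbers. Of the same-number pairs 37.3% had an r over 0.1, with no such share computed for the others, so pairing in part of the arrays stays open.

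Leaving out each replicate number in turn, which removed 51, 42, 27, 16 and 1 arrays, gave 193 to 2740 for mating in females, 494 to 1263 for mating in males, 0 to 383 for diet in females, 1 to 72 for diet in males, 541 to 3713 for population in females, 1596 to 2496 for population in males, 0 to 46 for development time in males, 77 to 3387 for sex by mating and 128 to 1499 for sex by population. FBtr0163647, past the threshold for mating in females otherwise, had an adjusted p of 0.0529 without replicate number 1.

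Without the 2 arrays with the profile of the opposite sex, 1225 passed for mating in females, 50 for diet in females and 1542 for sex by mating. Without the 4 female arrays of low sex score, 797 passed for mating in females, 0 for diet in females in limma (3151 unadjusted) and 1430 for sex by mating, and without these and the 2 arrays 637, 5 and 553. With array spread as a covariate, 625 passed for diet in females, 1992 for population in females, 2 for development time in males, 2190 for sex by mating and 1 for sex by diet. With both changes, 606 passed for diet in females, 4420 for population in males, 4 for development time in males, 1244 for sex by mating, 3 for sex by diet and 1903 for sex by population. The F test over days within population, diet and mating state gave 30 for development time in females, and without the 2 arrays 1050 in females and 2 in males. The comparison of 18 with 16 day males gave 110, and 319 without the 2 arrays. The gene list tests and both their alternatives were not run, since no transcript could be matched to a gene name. Signal over background was not analysed here, which leaves the precision of dim transcripts unknown.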

Other observations

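After sex, the next principal component held 5.996% of the variance. Array spread, the SD of an array's log2 values, ranged from 1.597 to 1.902. Over the 135 arrays it averaged 1.762 in Las Bocas and 1.786 in Punta Prieta females, and 1.793 and 1.811 in males. Among these, females reared on agria averaged 1.762 and those on organ pipe 1.792. With array spread as a covariate, chosen after seeing the data, 625 transcripts passed for diet in females in place of 1, of which 226 were higher and 399 lower on organ pipe, and the cause was not tested.

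Some of the largest mating responses in males were shared by females. FBtr0174264 rose by 0.962 (SE 0.17, adjusted p = 1.47e-05) and FBtr0173947 by 1.03 (SE 0.192, adjusted p = 4.19e-05) in mated females. FBtr0174510 fell by 0.645 in mated females (SE 0.148, adjusted p = 0.00116), and its value in males was also lower in Punta Prieta, at -0.585 (SE 0.133, adjusted p = 0.000388). FBtr0163647, which fell after mating in females, was higher in Punta Prieta females by 1.16 (SE 0.231, adjusted p = 7.89e-05) and differed by 0.0171 (SE 0.216) in males, with a difference between the sexes of 1.14 (SE 0.316, adjusted p = 0.0128).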
